A study of Homo sapiens with 24 samples.

How the data were processed

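PolyA RNA of 24 libraries from 4 lymphoma lines was sequenced as paired ends after stranded library preparation, per the labels' protocols. Base calling used bcl2fastq and the genome build was hg38, per the submitters' processing notes; the aligner, the counting tool and its strand setting are not given in the sources used here, so overlapping and antisense genes cannot be taken as separate. The authors' deposited table gives, for each of 31891 genes, the mean of log2(TPM + 1) in each of the 8 groups of line and treatment, per the file headers and the values. That the log2 levels in the deposited table are log2(TPM + 1) was tested on the values: raised to the power of 2 and lowered by 1 they sum in each group to just under the total that defines TPM. The shortfall was 0.62% in HBL1 with DMSO and between 0.05% and 0.21% in the other groups. The deposited table also gives the log2 fold change of GSK126 against DMSO in each line, which equals the difference of the 2 group means, the -log10 p-value and an adjusted p-value, which equals the Benjamini-Hochberg adjustment over all genes of the line. It gives the exon length of each gene. TPM values are printed as 2 to the power of the deposited log2 mean, minus 1, and are therefore close to geometric means. No value per library was used, so the text gives no SD over libraries and no result with a library left out.

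The 4 p-values and differences of a gene were used to recover its SE. For residual degrees of freedom between 10 and 22, the SE implied by each line was computed and compared between lines, and at 16 the 4 values agreed to within 1% for 100% of the 26202 genes with 2 or more informative differences. That is the residual of 1 model with 8 groups of 3 libraries and 1 spread per gene. An SE was recovered for 31884 genes. The median residual SD of genes at 1 TPM or more was 0.07 on the log2 scale. Because the spread is pooled over the 8 groups, a library that stands apart in 1 group widens the SE of that gene in every line. In the line of that group the pooled SE can still be too small. Depth was recovered from genes near 0 with a short exon length. Where such a gene had a single read in 1 library of a group and none in the others, its level times its exon length takes 1 of 3 fixed values, 1 per library. All 3 were found in each group, and between 95.1% and 99.7% of such low genes lay on one of them.

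Per-line results are the authors' adjusted p-values as deposited, at a threshold of 0.05. Differences of response between lines, and levels with DMSO, were tested as contrasts of the 8 group means in limma 3.58.1 (R 4.3.3), with the recovered residual SD moderated along a trend on mean level (prior degrees of freedom 2.69), over the 16007 genes at 1 TPM or more in at least 1 group and with Benjamini-Hochberg adjustment. This departs from the plan fixed before the data were examined. For a table of the authors' comparisons the plan had no test of differences of response, or a z test if the table gave standard errors, and it had tests of DMSO levels only with values per library. The moderated test was chosen after the SE proved recoverable, with 16 residual degrees of freedom behind it, and the z test is among the alternatives. limma is the tool behind each adjusted p of a difference between lines. Genes called in all 4 lines with one sign stand for the mean response. The script was tested on simulated data with 200 changed genes: it recovered the SE, and in a GSK126 against DMSO comparison in WSUDLCL2 over 16007 genes it called 93% of genes changed by 0.5 and 99% of those changed by 1 on the log2 scale, with 3.03% of the calls being unchanged genes. For the difference between mutant and wild-type lines the figures were 93%, 99% and 3.52%. The changed genes were drawn from those above a minimum level in all 4 lines, and each gene had normal noise of 1 spread in all groups. Both mutant lines were given the same change and both wild-type lines none. These figures therefore do not cover low genes, a library that stands apart, or lines of one genotype that differ in response. The share of unchanged genes among the calls says nothing about how often lines differ for reasons other than genotype.

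There were 24 gene lists, fixed with the plan: MHC class I presentation, MHC class II presentation, interferon response, PRC2 components and H3K27 demethylases, PRC2 developmental targets, germinal centre B cell, plasma cell, activated B cell like signature, NF-kB targets, B cell receptor signalling, proliferation, CDK inhibitors and growth arrest, cholesterol biosynthesis, fatty acid synthesis, T cell costimulation and checkpoint ligands, NK cell ligands, BCL2 family, integrated stress and unfolded protein response, B cell homing receptors, cancer testis antigens, T cell markers, myeloid markers, epithelial and stromal markers, and mitochondrial transcripts. Each list with at least 3 genes at 1 TPM or more in any group was set against 10000 random lists matched on mean level (10 bins), two-sided, adjusted over the 23 lists of a line; the smallest p these can give is 0.0002. Only 2 myeloid markers reached that level, and that list was not tested. The random lists treat genes as independent, and members of a list move together, so these p-values are too small by an amount that cannot be estimated without values per library. Fisher's exact test of the calls and cameraPR with a preset correlation of 0.01 were run beside them. Of 92 tests of a list in a line, 41 passed against random lists, 40 by cameraPR and 17 by Fisher's exact test, and 28 passed by both of the first 2, all in one direction. Between 8 and 14 lists passed in each line.

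Genes named in the text follow a rule set with the plan: genes always named (among them EZH2, HLA-B, HLA-C, B2M, NLRC5, CIITA, HLA-DRA, CD74, PRDM1, IRF4, BCL6 and CDKN1A); the 10 largest increases and 8 largest decreases of each line among protein-coding genes past the threshold at a mean of 1 TPM or more; up to 4 members of each list with the largest changes; the 6 largest differences of each sign for each contrast of responses; and, of protein-coding genes changed in all 4 lines at a mean of 1 TPM or more in each, the 10 whose smallest change was largest, to which 6 decreases were added after the data were seen. Some genes that the rule selects are not reported here, and others were left out where they repeated statistics or where copies or readthrough annotation made them unclear. Gene coordinates and types are from GENCODE 29 on the same build, in which 31735 of the identifiers were found. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The rescalings tried as alternatives multiply the TPM of the GSK126 group of a line by 1 factor, keep the SE and repeat the tests; one takes mitochondrial genes out of the total and one sets the median change of genes at 7 TPM or more to 0.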

Results

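Messenger RNA was measured by polyA-selected, strand-specific RNA sequencing in 4 human diffuse large B cell lymphoma lines that had been kept with the solvent DMSO or with GSK126, a small-molecule inhibitor of the histone methyltransferase EZH2, for 4 days. EZH2 is the catalytic subunit of PRC2, the complex that methylates lysine 27 of histone H3 at silenced genes. HBL1 belongs to the activated B cell like subtype and carries wild-type EZH2. WSUDLCL2, SUDHL4 and SUDHL5 belong to the germinal centre B cell like subtype. WSUDLCL2 carries the EZH2 change Y641F, SUDHL4 carries Y641S and SUDHL5 is wild type. HBL1, WSUDLCL2 and SUDHL4 received 4 µM GSK126 and SUDHL5 received 1.5 µM. Each of the 8 groups of line and treatment held 3 libraries, 24 in all. Depth recovered from the spacing of the lowest values lay between 26.7 M and 49.4 M reads or fragments per library. The table holds 31891 genes, of which 16007 reached 1 TPM in at least 1 group. All levels, log2 fold changes and per-line adjusted p-values below are from the authors' deposited table, the fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, and each standard error (SE) was recovered from the authors' p-values. Nothing says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

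The first comparison asked which genes GSK126 changed in each line. Increases of 2-fold or more outnumbered decreases of that size in each line, and most genes of MHC class II antigen presentation were higher with the inhibitor in all 4. WSUDLCL2 had the most changes of 2-fold or more, with 1257 genes higher and 483 lower in the authors' deposited table, or 1714 and 230 with the median change of genes at 7 TPM or more set to 0. Over all genes SUDHL4 had 416 higher and 17 lower, SUDHL5 had 271 and 7, and HBL1 had 215 and 16. Among genes at 7 TPM or more with DMSO, decreases led in WSUDLCL2, with 166 higher and 413 lower. Those counts were 211 and 282 without mitochondrial genes and 312 and 182 with that median set to 0. In each of the other lines increases led at that level too. With no minimum size, at an adjusted p under 0.05, 12280 genes changed in WSUDLCL2 (6007 rose and 6273 fell), 9015 in SUDHL4 (5044 and 3971), 8141 in HBL1 (5193 and 2948) and 7308 in SUDHL5 (5046 and 2262). Many of these changes were small, because the spread between libraries was small: at the median SE of 0.06 a log2 fold change of 0.13 reached an unadjusted p of 0.05. The direction of small changes depends on the scaling. Genes at 7 TPM or more had a median log2 fold change of -0.23 in WSUDLCL2, -0.08 in SUDHL4, -0.02 in HBL1 and 0.01 in SUDHL5. With those medians set to 0, the share of increases went from 48.9% to 66.1% of the calls in WSUDLCL2 and from 56.0% to 67.2% in SUDHL4. With mitochondrial genes left out of the total instead, the WSUDLCL2 median moved to -0.12.

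**Figure D1:**
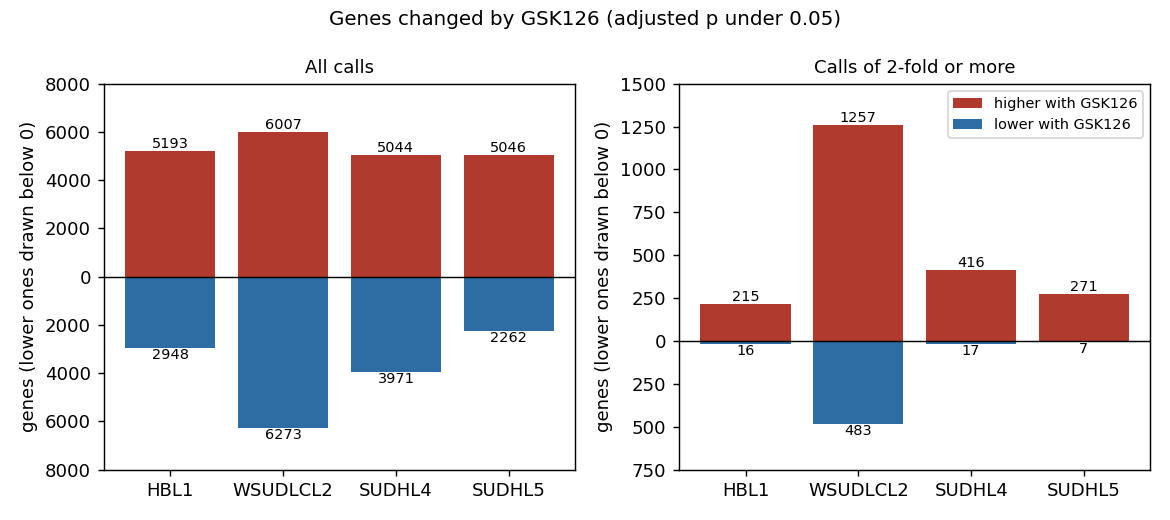
Bars give the number of genes called in the authors' deposited table at an adjusted p under 0.05 in each line, higher with GSK126 above 0 and lower below 0, on the left for all calls and on the right for calls of 2-fold or more. WSUDLCL2 has the tallest bars on the right, 1257 higher and 483 lower, and the other 3 lines have 7 to 17 genes lower by that much.

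In WSUDLCL2, most genes of the germinal centre B cell, B cell receptor signalling and plasma cell lists rose with GSK126. Most NF-kB targets and all genes of the proliferation list fell. TCL1A, a coactivator of the AKT kinase in B cells, went from 0.203 to 50.8 TPM, a log2 fold change of 5.43 ± 0.06 (adjusted p = 9.42e-19) in the authors' deposited table. The other large increases were in the growth factor gene BMP7 (4.68 ± 0.06), S100A10 (4.24 ± 0.10), the cannabinoid receptor gene CNR1 (4.24 ± 0.07), EEF1A2 (4.07 ± 0.12), PARM1 (3.99 ± 0.07), ALDH2 (3.74 ± 0.05), CD24 (3.65 ± 0.07), the metallothionein gene MT1G (3.63 ± 0.07) and TUBB2B (3.61 ± 0.18). The largest decreases were in EBI3, a cytokine subunit (-2.94 ± 0.15 (adjusted p = 3.48e-11)), the anti-apoptotic gene BCL2A1 (-2.83 ± 0.12), the cystine transporter gene SLC7A11 (-2.66 ± 0.08), the cytokine genes LTA (-2.57 ± 0.11) and TNF (-2.45 ± 0.08), TRIP10 (-2.33 ± 0.11), CD1C (-2.22 ± 0.20) and the replication-linked gene DTL (-2.09 ± 0.05). All 25 members of the proliferation list fell, with a median log2 fold change of -1.21. RRM2, a subunit of ribonucleotide reductase, fell by 1.65 on the log2 scale, PCNA by 1.62 and the cyclin gene CCNA2 by 1.54, and the list median lay below random lists matched on level (adjusted p = 0.00115). Of the NF-kB targets 5 of 19 members rose and 13 fell (5 and 13 adjusted over the list alone), and the list median of -0.50 also lay below random lists (adjusted p = 0.00263). ICAM1 fell by 1.68 and NFKB2 by 1.39. Of the germinal centre B cell list 9 of 16 members rose and 2 fell (10 and 2 adjusted over the list alone), among them the repressor gene BACH2 (10.7 to 93.5 TPM). That list lay above random lists (adjusted p = 0.00115), as did B cell receptor signalling (adjusted p = 0.00263), where 13 of 17 members rose and 2 fell (13 and 3 adjusted over the list alone), the kinase gene PRKCB by 2.58. CDKN1A, which encodes the cell cycle inhibitor p21, went from 0.881 to 7.70 TPM, and BTG2 and BTG1 rose by 1.21 and 1.15, while CDKN2D fell by 1.22. The list of CDK inhibitors and growth arrest genes lay above random lists (adjusted p = 0.00263, against 0.258 by cameraPR), with 6 of 10 members higher and 3 lower. The plasma cell list did too (adjusted p = 0.0195), with FAM46C at 2.13, JCHAIN at 1.22 and TNFRSF17 at 1.14. EZH2 itself fell by 0.57 (adjusted p = 2.67e-11), or by 0.46 without mitochondrial genes and 0.35 with the median change of genes at 7 TPM or more set to 0. IRF4, a transcription factor gene of the plasma cell program, fell by 0.76 from a level of 1.89 TPM. Of the PRC2 developmental targets 12 of 21 members rose and 0 fell (12 and 0 adjusted over the list alone), with BMP7 and WNT5A (1.85) in front, and the list missed the threshold (adjusted p = 0.117, against 0.00434 by cameraPR with a preset correlation). The mitochondrial share of TPM was 15.6% with DMSO and 22.0% with GSK126 in this line.

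In SUDHL4, the other EZH2 mutant line, the largest increases included an MHC class I gene, and proliferation genes fell by less than in WSUDLCL2. The pore-forming protein gene MPEG1 went from 2.99 to 48.3 TPM, a log2 fold change of 3.63 ± 0.10 (adjusted p = 6.70e-14) in the authors' deposited table. It was followed by FABP6 (2.88 ± 0.08), CNR1 (2.86 ± 0.07), HLA-B (2.79 ± 0.04), TBC1D4 (2.58 ± 0.07), SH3BP5 (2.47 ± 0.05), ELOVL2 (2.40 ± 0.07), FNBP1 (2.40 ± 0.04), ANKRD33B (2.35 ± 0.04) and the germinal centre marker gene LMO2 (2.34 ± 0.03). The largest decreases were in MAP6D1 (-1.50 ± 0.31), RSC1A1 (-1.24 ± 0.21), DTL (-1.13 ± 0.05), the adhesion gene MCAM (-1.11 ± 0.05), LRRC4 (-1.03 ± 0.05) and E2F2 (-1.03 ± 0.04). Of the B cell receptor signalling list 13 of 17 members rose and 0 fell (13 and 0 adjusted over the list alone), with PRKCB at 2.30 and the phosphatase gene PTPN6 at 2.18, and the list lay above random lists (adjusted p = 7.67e-04). The germinal centre list (10 of 16 higher, adjusted p = 7.67e-04), the NF-kB targets (10 of 19 higher, adjusted p = 0.00690) and the CDK inhibitors (7 of 10 higher, adjusted p = 7.67e-04) lay above random lists as well. BCL2A1, an NF-kB target, rose by 1.43 and CDKN1A by 2.03. Of the T cell costimulation and checkpoint ligands 12 of 18 members rose and 2 fell (14 and 2 adjusted over the list alone) (adjusted p = 7.67e-04), with CD70 at 1.45, CD40 at 0.91 and TNFRSF14 at 0.84. The BCL2 family (8 of 15 higher, adjusted p = 0.0143, against 0.133 by cameraPR) and cholesterol biosynthesis (13 of 21 higher, adjusted p = 0.00197) passed too, the BH3-only gene BMF rising by 1.06 and the sterol transport gene STARD4 by 0.75. In the proliferation list 20 of 25 members fell and none rose, with a median of -0.35 (adjusted p = 7.67e-04), MCM6 falling by 0.80 and PCNA by 0.69. EZH2 fell by 0.25, or by 0.17 with the median change of genes at 7 TPM or more set to 0. BMP7 and SOX9, both PRC2 developmental targets, rose by 1.63 and 1.61, and that list missed the threshold (adjusted p = 0.0931, against 0.0387 by cameraPR). The mitochondrial share of TPM was 15.5% with DMSO and 17.5% with GSK126.

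In SUDHL5, wild type for EZH2 and given the lower dose, plasma cell, MHC class I and cholesterol genes rose. FCRL3, an Fc receptor-like gene of B cells, went from 3.86 to 55.3 TPM, a log2 fold change of 3.54 ± 0.07 (adjusted p = 5.38e-16) in the authors' deposited table. L3MBTL4 (2.50 ± 0.07), AFF1 (2.47 ± 0.04), FILIP1L (2.43 ± 0.06), SPOCK1 (2.23 ± 0.04), GATM (2.22 ± 0.04), RCAN2 (2.10 ± 0.09), the cytokine gene IL10 (2.07 ± 0.15), HLA-B (2.07 ± 0.04) and CNR1 (2.05 ± 0.07) came next. The largest decreases were smaller, in RGS1 (-1.07 ± 0.10), the integrin activator gene FERMT3 (-1.04 ± 0.05), DLGAP1 (-0.97 ± 0.05), NECTIN1 (-0.96 ± 0.06), BFSP2 (-0.91 ± 0.08), FAM167A (-0.91 ± 0.03) and SASH3 (-0.89 ± 0.05). Of the plasma cell list 16 of 19 members rose and 1 fell (16 and 1 adjusted over the list alone) (adjusted p = 9.20e-04), with FAM46C at 1.49, TNFRSF17, which encodes the receptor BCMA, at 1.31 and JCHAIN at 0.88. Of the activated B cell like signature 10 of 16 members rose and 0 fell (12 and 0 adjusted over the list alone) (adjusted p = 0.00287), IL10 first, then RAB29 (1.59), ETV6 (1.47) and STAT3 (0.96). In SUDHL4 11 members of that list rose and 0 fell (adjusted p = 0.0606, against 2.90e-05 by cameraPR). In WSUDLCL2 9 rose and 4 fell (adjusted p = 0.341, against 0.0158 by cameraPR), and in HBL1 5 rose and 1 fell (adjusted p = 0.471, against 0.679 by cameraPR). Cholesterol biosynthesis (17 of 21 higher and none lower, adjusted p = 9.20e-04), the interferon response (31 of 41 higher, adjusted p = 9.20e-04) and the germinal centre list (9 of 16 higher, adjusted p = 0.00153) lay above random lists, with STARD4 at 0.77, OAS1 at 1.02 and LMO2 at 0.82. So did PRC2 developmental targets (adjusted p = 0.0202, 10 of 21 higher, WNT5A by 0.87). NF-kB targets (adjusted p = 0.0120), CDK inhibitors (0.00767), the BCL2 family (0.0180) and the integrated stress and unfolded protein response (0.0283, HSPA5 by 0.49) passed against random lists and not by cameraPR, where their adjusted p were 0.126, 0.355, 0.0923 and 0.619. CDKN1A rose by 0.62 and EZH2 fell by 0.14. Of the proliferation list 2 of 25 members rose and 14 fell (2 and 17 adjusted over the list alone), and the list as a whole missed the threshold (adjusted p = 0.0897, against 1.56e-05 by cameraPR). The T cell marker list, of which 5 genes were measured, lay below random lists (adjusted p = 0.00287), with LCK at -0.64 and TRAC at -0.51. The mitochondrial share of TPM was 15.04% with DMSO and 16.1% with GSK126.

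In HBL1, the activated B cell like line, interferon response genes rose as a group. Of that list 39 of 41 members rose and 0 fell (39 and 0 adjusted over the list alone), with a median log2 fold change of 0.86 (adjusted p = 0.00115) in the authors' deposited table. CMPK2 rose by 1.36, the antiviral gene IFIT3 by 1.28, EPSTI1 by 1.25 and PARP9 by 1.21. The largest single increase was in SPP1, which encodes osteopontin, from 1.73 to 18.9 TPM, a log2 fold change of 2.87 ± 0.09 (adjusted p = 2.65e-13). CAV1, which encodes caveolin (2.19 ± 0.03), FILIP1L (2.06 ± 0.06), the B cell chemokine gene CXCL13 (2.03 ± 0.10), SIGLEC6 (2.00 ± 0.06) and PTGER4 (1.65 ± 0.08) were also among the largest. CT45A6 (2.32 ± 0.58), CCL3L3 (1.70 ± 0.17) and CCL4L2 (1.67 ± 0.13) belong to families of near-identical copies that can share reads, so their values are uncertain. The largest decreases were in HTR3B (-1.34 ± 0.08), IZUMO4 (-1.21 ± 0.07), CAMP (-1.12 ± 0.11), the quiescence factor gene KLF2 (-1.10 ± 0.14), HES1 (-1.05 ± 0.11) and TNF (-0.91 ± 0.08), and MAGED4 (-1.62 ± 0.38) has a near-identical copy. T cell costimulation and checkpoint ligands (adjusted p = 0.00276), NF-kB targets (adjusted p = 0.00307), fatty acid synthesis (adjusted p = 0.0171) and B cell homing receptors (adjusted p = 0.0213) lay above random lists. By cameraPR fatty acid synthesis passed (adjusted p = 0.00894) and the costimulation (0.177), NF-kB (0.395) and homing (0.168) lists did not. CD274, which encodes PD-L1, rose by 0.64, the chemokine gene CCL22 by 1.24 and the fatty acid gene ACSS2 by 1.24. TNF, which is not on the NF-kB list, is among the genes that fell. The proliferation list lay below random lists (adjusted p = 0.0480), with 18 of 25 members lower and a median of -0.19. EZH2 had a log2 fold change of 0.02 ± 0.03 and did not pass (adjusted p = 0.813), nor did CDKN1A (0.20 ± 0.13, adjusted p = 0.339). PRDM1 and BCL6, opposing regulators of plasma cell and germinal centre fate, rose by 0.24 and 0.41. COL3A1 and COL1A2, from the list of epithelial and stromal markers, rose by 1.54 and 1.53, and that list, with 4 of 6 genes higher and 0 lower, missed the threshold against random lists (adjusted p = 0.272) and passed by cameraPR (1.07e-07). The mitochondrial share of TPM was 11.04% with DMSO and 14.04% with GSK126. In 1 of the 3 DMSO libraries of this line, 766 genes of short exon length had a single read there and none in its partners, against 491 and 503 in the others.

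Antigen presentation genes were the focus of the next comparison, since the lines were examined for how EZH2 inhibition acts on MHC expression. HLA-B, which encodes a classical class I heavy chain (chromosome 6, 31269491 to 31357188, hg38), rose in all 4 lines in the authors' deposited table. It went from 20.5 to 148 TPM in SUDHL4 (2.79 ± 0.04 (adjusted p = 3.17e-17)), from 117 to 494 in SUDHL5 (2.07 ± 0.04 (adjusted p = 8.74e-16)), from 49.96 to 205 in WSUDLCL2 (2.01 ± 0.04 (adjusted p = 1.76e-16)) and from 352 to 555 in HBL1 (0.66 ± 0.04 (adjusted p = 1.80e-09)). HLA-C rose by 0.54 to 0.91 and HLA-E by 0.19 to 0.95. NLRC5, the transactivator of class I genes (chromosome 16, 56989485 to 57083531), rose by 1.86 ± 0.05 in WSUDLCL2, 1.18 ± 0.05 in SUDHL4, 0.70 ± 0.05 in SUDHL5 and 0.51 ± 0.05 in HBL1. The other class I genes parted between lines. B2M, the class I light chain, rose in SUDHL5 (0.37 ± 0.03) and HBL1 (0.33 ± 0.03), fell in WSUDLCL2 (-0.36 ± 0.03, or -0.25 without mitochondrial genes and -0.13 with the median change of genes at 7 TPM or more set to 0) and had 0.07 ± 0.03 in SUDHL4, which did not pass (adjusted p = 0.0729) but passed under both other scalings. The peptide transporter gene TAP1 rose by 0.81 in HBL1 and 0.57 in SUDHL5 and fell by 0.90 in WSUDLCL2, where the immunoproteasome gene PSMB9 fell by 1.51. Of the 21 class I presentation genes, 15 rose and 0 fell in SUDHL5, 14 rose and 3 fell in HBL1, 10 rose and 6 fell in SUDHL4, and 4 rose and 14 fell in WSUDLCL2; adjusted over the list alone the counts were 16 and 0, 14 and 3, 11 and 6, and 4 and 14. The list lay above random lists in HBL1 (adjusted p = 0.00115) and SUDHL5 (adjusted p = 9.20e-04). In SUDHL4 it missed the threshold (adjusted p = 0.0556) and passed by cameraPR (2.38e-04). In WSUDLCL2 its median of -0.28 was near the -0.25 of random lists (adjusted p = 0.861), and that median was -0.17 without mitochondrial genes and -0.05 with the median change of genes at 7 TPM or more set to 0.

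Most class II presentation genes rose in every line. HLA-DRA (chromosome 6, 32439842 to 32445046) rose by 0.89 ± 0.03 in SUDHL4, 0.64 ± 0.03 in HBL1, 0.59 ± 0.03 in WSUDLCL2 and 0.51 ± 0.03 in SUDHL5 in the authors' deposited table. CD74, the invariant chain, rose by 0.29 to 0.56 and HLA-DOA by 0.65 to 1.26. CIITA, the transactivator of class II genes (chromosome 16, 10866222 to 10943021), rose in WSUDLCL2 (0.64 ± 0.04), SUDHL4 (0.58 ± 0.04) and SUDHL5 (0.34 ± 0.04), and in HBL1 it had 0.06 ± 0.04 (adjusted p = 0.259). HLA-DMB rose by 0.85 in WSUDLCL2 and 0.65 in SUDHL4 and fell by 0.33 in HBL1 and 0.34 in SUDHL5. Of the 18 class II genes, 16 rose and 1 fell in SUDHL4, 15 rose and 2 fell in WSUDLCL2, 12 rose and 2 fell in HBL1 and 10 rose and 3 fell in SUDHL5, and adjusted over the list alone these counts were equal. The list lay above random lists in SUDHL4 (adjusted p = 7.67e-04), SUDHL5 (adjusted p = 9.20e-04), HBL1 (adjusted p = 0.00115) and WSUDLCL2 (adjusted p = 0.00115). HLA alleles differ from the reference genome and resemble each other, and the annotated span of HLA-B covers part of HLA-C on the same strand, so reads can have been split between HLA genes.

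**Figure D2:**
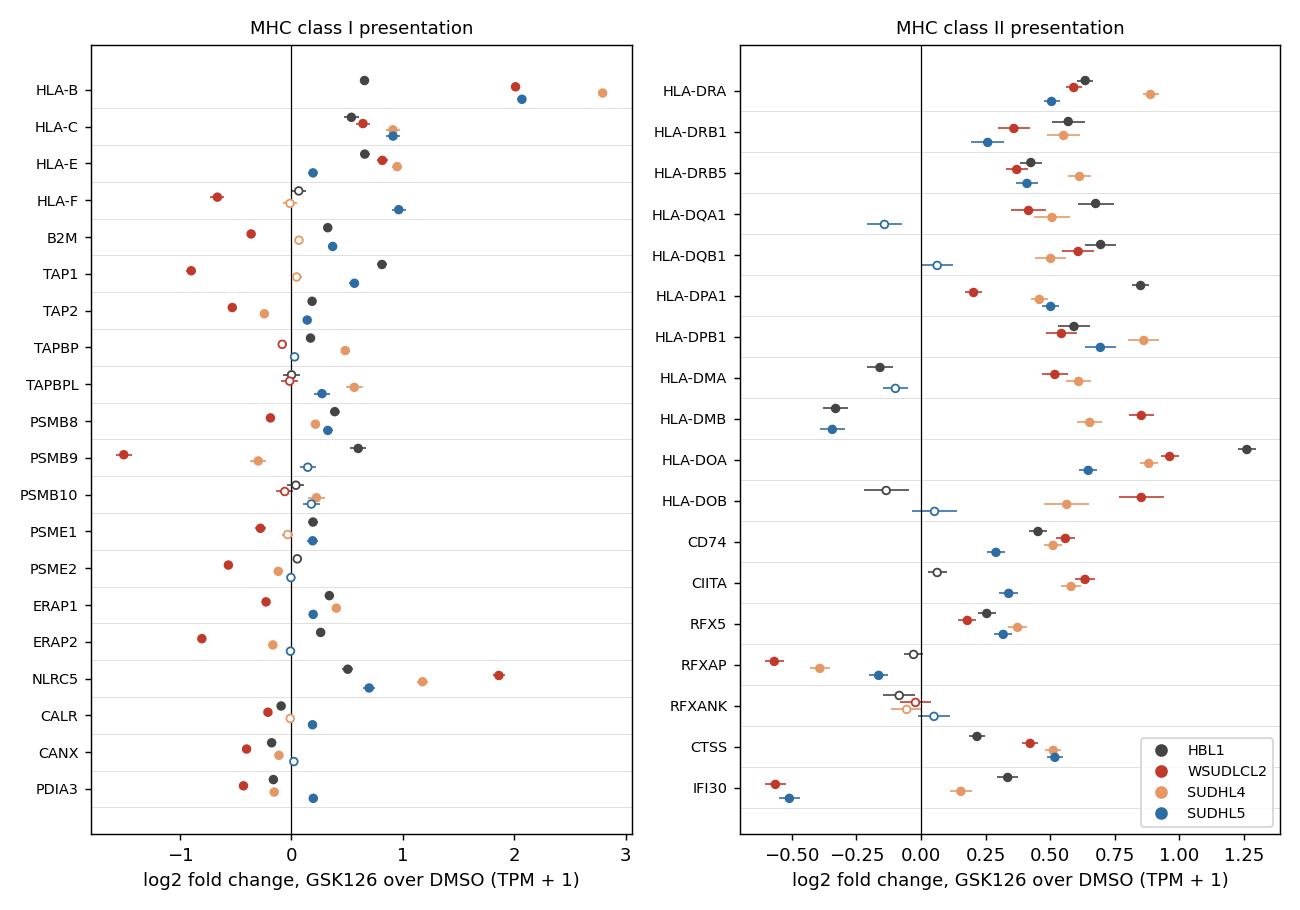
Points give the log2 fold change of GSK126 over DMSO (horizontal axis, TPM + 1) of genes of the 2 antigen presentation lists in the 4 lines, with bars for the recovered SE; filled points passed an adjusted p of 0.05 and open points did not. HLA-B and NLRC5 lie to the right of 0 in every line, while WSUDLCL2 lies to the left of 0 for most class I genes that passed.

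The levels of these genes with DMSO were compared between lines to show where each started. HBL1 had the highest HLA-B, at 352 TPM, against 117 in SUDHL5, 49.96 in WSUDLCL2 and 20.5 in SUDHL4 in the authors' deposited table. HBL1 also had the highest NLRC5, at 24.6 TPM, while WSUDLCL2 and SUDHL4 had 0.575 and 0.592. For class II the order was opposite, with HLA-DRA at 92.6 TPM in HBL1 and 1151, 1367 and 1399 in SUDHL5, WSUDLCL2 and SUDHL4. In limma on the recovered model, HBL1 was higher than the 3 germinal centre lines for 16 of 21 class I genes and lower for 4. It was lower for 17 of 18 class II genes and higher for 1. The EZH2 mutant lines were lower than the wild-type lines for 16 class I genes and higher for 4, with HLA-B at -2.63 ± 0.03 (SE, adjusted p = 1.83e-24) and NLRC5 at -2.80 ± 0.04 on the log2 scale, and higher for 16 class II genes and lower for 2. Both wild-type lines were above both mutant lines in HLA-B, HLA-C and NLRC5. For HLA-DRA the difference between genotypes lies with HBL1, since SUDHL5 was close to both mutant lines. HBL1 carries other calls in these counts too. B2M and CALR, counted as lower in the mutant lines, were lowest in SUDHL5 (493 and 691 TPM). HLA-DQA1, counted as higher in the mutant lines, was highest in SUDHL5 (87.5 TPM). Genotype has 2 lines on each side, so differences between lines for any other reason are part of these values.

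Genes that changed in the same direction in all 4 lines numbered 1149 that rose and 942 that fell in the authors' deposited table, where independent lists would share 24.5 and 5.12. Among the 16007 genes at 1 TPM or more the shared counts were 1130 and 942, against 88.2 and 33.5 for independent lists. Of the named genes of this kind with the largest smallest change, PTMS, which encodes parathymosin, rose by 1.17 to 2.06, the G protein gene GNAZ by 1.10 to 2.51, FCRL3 by 1.07 to 3.54 and the guanine exchange factor gene DOCK9 by 1.04 to 1.67. MSRB2, PKIA, MEX3A, BLVRA, STRADB and THRA rose by at least 0.90 in each line. These 4 leading genes, TCAF1 and the HLA-region transcript HCP5 were the 6 genes that rose 2-fold or more in every line; TCAF1 and HCP5 were named after their values were seen. The phosphatase gene CDC25A, a driver of cell cycle entry, fell by 0.61 to 1.84, the telomerase gene TERT by 0.56 to 0.92, ZNF724 by 0.45 to 1.08, and PDCD2L, NUP160 and ATAD3B by at least 0.41. Across the 16007 genes, the log2 fold changes of the 2 mutant lines had a Pearson correlation of 0.653 (Spearman 0.717), and the other 5 pairs of lines had 0.325 to 0.432. These are correlations across genes, which are not independent replicates. The 2 mutant lines are also the only pair alike in both subtype and dose, so their higher correlation cannot be credited to genotype. WSUDLCL2 and SUDHL4 shared 253 genes that rose 2-fold or more, where independent lists would share 32.7, and WSUDLCL2 and SUDHL5 shared 141, against 21.3. The calls of a gene in the 4 lines rest on 1 pooled SE, so a gene of small SE tends to be called in every line. Unrelated responses would thus share more genes than the independent lists of this paragraph, by an amount that was not estimated.

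**Figure D3:**
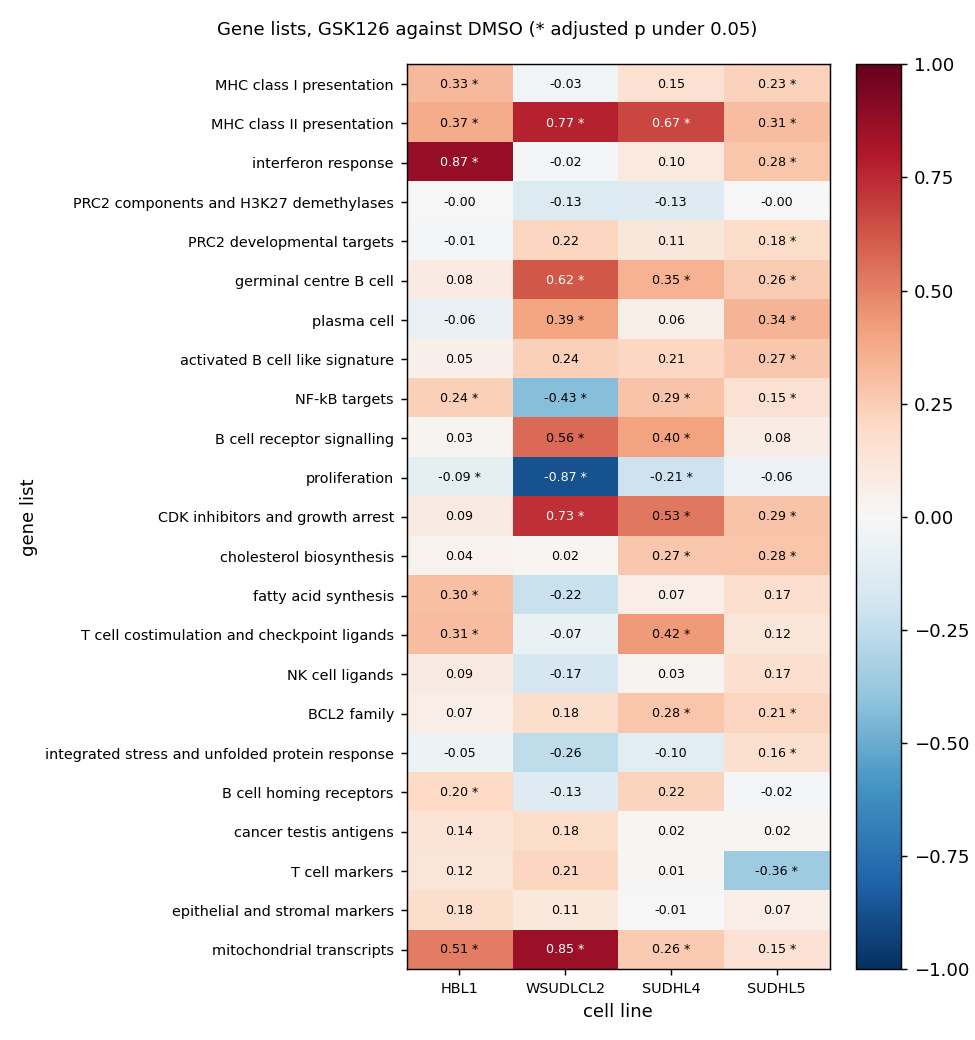
Each cell gives the median log2 fold change of a gene list (rows) in a line (columns), minus the median of random lists matched on level, and an asterisk marks an adjusted p under 0.05. MHC class II presentation is marked in all 4 lines, NF-kB targets are below random lists in WSUDLCL2 and above them in the other 3 lines, and proliferation is marked below them in HBL1, WSUDLCL2 and SUDHL4.

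The design also asked whether lines with mutant EZH2 responded differently from lines with wild-type EZH2. The SE and p-values of each contrast of responses come from the spread between libraries within lines. They leave out the spread between lines of one genotype, so they describe these lines and not the genotypes. The response of CDKN1A was larger in the mutant lines, by 1.71 ± 0.12 on the log2 scale (SE, limma adjusted p = 3.15e-10), as were those of HLA-B (1.04 ± 0.04), NLRC5 (0.92 ± 0.05) and CIITA (0.41 ± 0.04). For HLA-B this is a difference of means, since it rose by 2.01 in WSUDLCL2 and 2.07 in SUDHL5. The largest differences of this sign were in BMP7 (3.03 ± 0.06), TCL1A (2.88 ± 0.06), CNR1 (2.53 ± 0.07), CD24 (2.45 ± 0.06), LHFPL2 (2.35 ± 0.07) and the ER-phagy receptor gene RETREG1 (2.32 ± 0.08). On the other side were FILIP1L (-1.96 ± 0.07), SLC7A11 (-1.89 ± 0.08), MCAM (-1.83 ± 0.05), EBI3 (-1.79 ± 0.15), the migration receptor gene GPR183 (-1.63 ± 0.08) and the galectin gene LGALS1 (-1.60 ± 0.08). Some of these means rest largely on single lines: EBI3, GPR183 and LGALS1 had -2.94, -1.83 and -1.41 in WSUDLCL2 and -0.07, -0.02 and -0.20 in SUDHL4, GPR183 and LGALS1 also rose in HBL1 by 1.10 and 1.61, and TCL1A had 5.43 in WSUDLCL2, 0.88 in SUDHL4 and 0.58 in SUDHL5. BMP7 had 4.68 in WSUDLCL2 and 1.63 in SUDHL4, and SLC7A11 had -2.66 and -0.73. CNR1 rose in all 3 germinal centre lines, by 4.24 in WSUDLCL2, 2.86 in SUDHL4 and 2.05 in SUDHL5, and had -0.01 in HBL1, so its difference owes much to HBL1. FILIP1L rose by 2.06 and 2.43 in the wild-type lines and by 0.50 in WSUDLCL2. B2M had a difference of -0.50 ± 0.03, since it fell in WSUDLCL2 and rose in both wild-type lines. HLA-C had 0.05 ± 0.06 (adjusted p = 0.495) and BCL6 -0.04 ± 0.03 (adjusted p = 0.265), which did not pass. All 25 proliferation genes responded more negatively in the mutant lines, with a median difference of -0.65, as did 13 of 19 NF-kB targets and 27 of 41 interferon response genes, while 13 of 17 B cell receptor signalling genes responded more positively. Without HBL1 the interferon list had 15 genes with a more negative and 9 with a more positive response, or 11 and 11 with the medians set to 0, so its difference rests on HBL1. Most of the proliferation difference comes from WSUDLCL2, where the list median was -1.21, against -0.35 in SUDHL4, -0.19 in HBL1 and -0.13 in SUDHL5. The NF-kB difference rests on WSUDLCL2, where the list median was -0.50, against 0.29 in SUDHL4, 0.19 in HBL1 and 0.16 in SUDHL5. In total 10042 of 16007 genes passed, 3635 with a more positive and 6407 with a more negative response in the mutant lines, and 426 differed by 2-fold or more. With the median change of genes at 7 TPM or more set to 0 in each line, the 2 directions held 5324 and 4263 genes, so the balance of directions is not settled by these data. The mutant and wild-type pairs also differ in subtype and dose, because HBL1 is the activated B cell like line and SUDHL5 received less GSK126.

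Within the germinal centre lines, WSUDLCL2 and SUDHL4 were compared with SUDHL5. CD24 (2.97 ± 0.08), BMP7 (2.88 ± 0.07), RETREG1 (2.58 ± 0.10), TCL1A (2.57 ± 0.07), the endocytosis gene EHD3 (2.47 ± 0.07) and S100A10 (2.46 ± 0.12) responded more positively in the mutant lines. All 6 responses were larger in WSUDLCL2 than in SUDHL4, and those of TCL1A and S100A10 came mostly from WSUDLCL2: S100A10 had 4.24 there, 0.62 in SUDHL4 and -0.03 in SUDHL5. FILIP1L (difference -2.14 ± 0.08) and IL10 (-2.06 ± 0.18) rose mainly in SUDHL5, while the negative differences of SLC7A11 (-2.08 ± 0.10), TRIP10 (-2.02 ± 0.13) and CD1C (-1.85 ± 0.23) came in large part from falls in WSUDLCL2, and the histone gene HIST2H2AA4 (-2.38 ± 0.99, adjusted p = 0.0479) has a near-identical copy. The difference in HLA-B was 0.33 ± 0.05, smaller than when HBL1 was among the wild-type lines, and the CDKN1A difference was 1.50 ± 0.15. Of the 18 class II genes 11 responded more positively in the mutant lines and 2 more negatively, and of the 21 class I genes 4 responded more positively and 14 more negatively. limma called 9123 genes, 3132 with a more positive and 5991 with a more negative response in the mutant lines, and with the medians set to 0 the 2 directions held 4618 and 3700. SUDHL5 received 1.5 µM against 4 µM in the other lines, so dose and genotype cannot be told apart here.

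The 2 mutant lines were compared with each other to show how far lines with mutant EZH2 differ. They carry different substitutions, Y641F in WSUDLCL2 and Y641S in SUDHL4, so a difference between them can also reflect the substitution. Most NF-kB targets responded differently in the 2 lines. The largest negative difference was in TNF, rising by 1.90 in SUDHL4 and falling in WSUDLCL2 (difference -4.35 ± 0.11, limma adjusted p = 2.25e-16). BCL2A1 (-4.26 ± 0.16), LTA (-4.11 ± 0.14), EBI3 (-2.87 ± 0.21), ANKRD33B (-2.93 ± 0.05) and SIRPA, which encodes the CD47 receptor (-2.85 ± 0.08), also responded more negatively in WSUDLCL2. TCL1A (4.55 ± 0.08), PARM1 (3.65 ± 0.10), S100A10 (3.62 ± 0.14), TUBB2B (3.57 ± 0.24), SPINT2 (3.28 ± 0.07) and RUBCNL (3.24 ± 0.10) responded more positively there. Of the 19 NF-kB targets 16 responded more negatively in WSUDLCL2 and 1 more positively, and with the medians set to 0 the counts were 14 and 1. Of the 21 class I presentation genes 19 responded more negatively, or 14 with the medians set to 0, among them PSMB9 (-1.21 ± 0.10), TAP1 (-0.95 ± 0.06) and B2M (-0.43 ± 0.04). NLRC5 responded more in WSUDLCL2 (0.69 ± 0.08) and HLA-B less (-0.78 ± 0.06), while CDKN1A (0.17 ± 0.17, adjusted p = 0.438) and CIITA (0.05 ± 0.06, adjusted p = 0.488) did not pass. All 25 proliferation genes fell further in WSUDLCL2, under both scalings. limma called 8097 genes, and 809 differed by 2-fold or more.

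**Figure D4:**
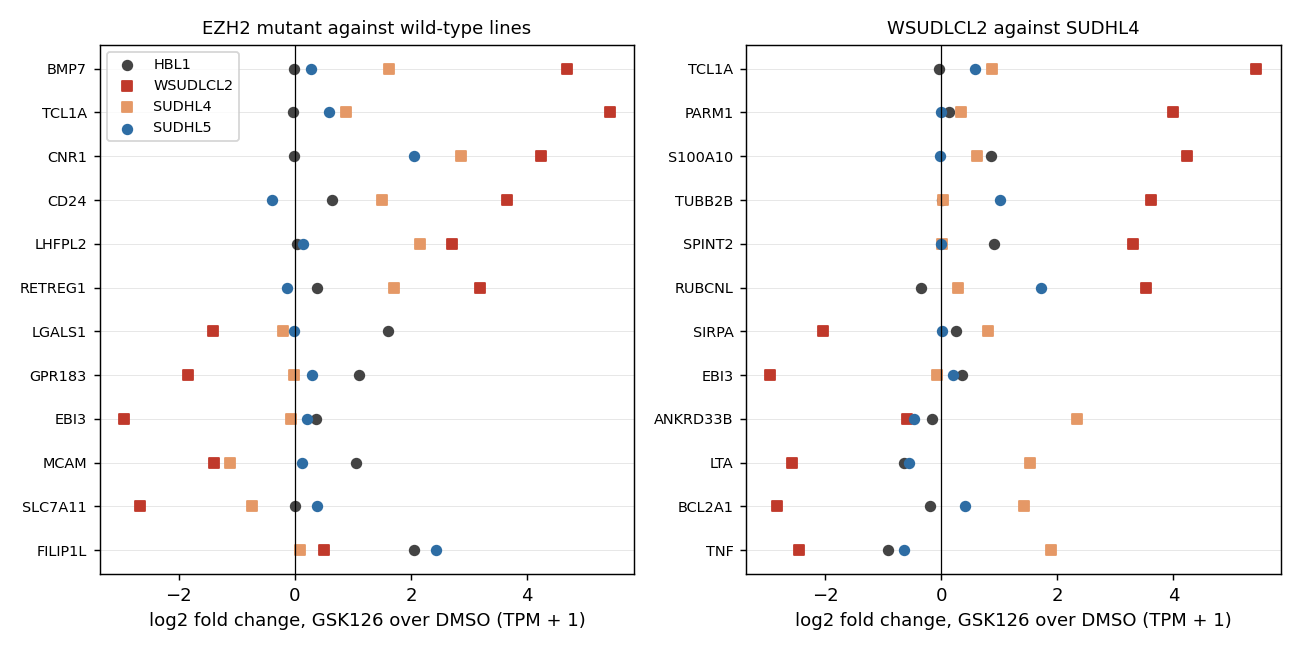
Points give the log2 fold change of GSK126 over DMSO (horizontal axis, TPM + 1) in each line for the genes whose responses differed most between EZH2 mutant (squares) and wild-type (circles) lines, on the left, and between WSUDLCL2 and SUDHL4, on the right. TNF, LTA and BCL2A1 lie on opposite sides of 0 in WSUDLCL2 and SUDHL4.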

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

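All tests of explanations in this part were chosen after the results they bear on had been seen, and explanations were split and replaced after their own outcomes were known. The scale floor was first tested over the 4 lines together, where 3 of 4 lines spoke against it as the only source and no decision was reached, and was then split by line. For the fall of class I genes in WSUDLCL2, 2 explanations were tested and then replaced: reads shared between HLA genes, which 12 of the 14 genes not being HLA genes spoke against, and lower NF-kB target expression, which spoke in favour, with a list median of -0.50 (adjusted p = 0.00263). The fall of NF-kB targets in this line was already known, and it does not link them to the class I genes, so nothing is concluded from it. Tests of the mitochondrial share and of the EZH2 mutation on the 14 genes alone were void, because those genes were chosen for having fallen, as was a test of the list median against the SD over genes; counts over the whole list replaced them. A test of the mitochondrial share for changes of 2-fold or more was void and dropped, because taking out a share that went up in every line can only add increases.

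Responses to GSK126 differed between lines by a test of the difference for 10042 genes between EZH2 mutant and wild-type lines, 9123 between mutant and wild-type germinal centre lines and 8097 between the 2 mutant lines. That test uses the spread between libraries within lines and leaves out the spread between lines of one genotype. Among the genes always named, the mutant minus wild-type difference in log2 response was 1.71 for CDKN1A, 1.04 for HLA-B, 0.92 for NLRC5, 0.41 for CIITA, 0.17 for HLA-DRA, 0.16 for CD74, -0.27 for PRDM1, -0.27 for IRF4, -0.35 for EZH2 and -0.50 for B2M. With the median change of genes at 7 TPM or more set to 0 they were, in the same order, 1.84, 1.19, 1.04, 0.55, 0.32, 0.31, -0.27, -0.23, -0.20 and -0.35. PRDM1 was nearly silent in both mutant lines, at 0.0123 and 0.0151 TPM with DMSO and GSK126 in WSUDLCL2 and 0 and 0.00928 in SUDHL4, so its difference comes from the wild-type lines alone. IRF4 was at 0.0925 TPM in SUDHL4 and 0.180 in SUDHL5 with DMSO. The largest positive differences were 3.03 for BMP7, 2.88 for TCL1A, 2.53 for CNR1, 2.45 for CD24, 2.35 for LHFPL2 and 2.32 for RETREG1. The largest negative ones were -1.96 for FILIP1L, -1.89 for SLC7A11, -1.83 for MCAM, -1.79 for EBI3, -1.63 for GPR183 and -1.60 for LGALS1. Between the 2 mutant lines, the WSUDLCL2 minus SUDHL4 difference was -1.21 for PSMB9, -0.95 for TAP1 and -0.43 for B2M, or -1.06, -0.80 and -0.27 with the medians set to 0. None of these genes changed the sign of its difference under that scaling. The 4 lines can be split into pairs in 3 ways, and the split by genotype gave 10042 genes against 7767 for the highest other split; it was 1 of 3 with as many genes, and 3 splits are too few for a share under 0.05. The 3 libraries of a group could not be regrouped, because no value per library was used.

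In WSUDLCL2, 14 of 21 class I presentation genes fell while HLA-B, HLA-C, HLA-E and NLRC5 rose. A larger mitochondrial share of TPM does not account for all of this, since 13 of the 21 genes still fell and 4 rose with mitochondrial genes taken out of the total. Mutant EZH2 as such does not account for it alone, since in SUDHL4, the other mutant line, 6 of the 21 genes fell and 10 rose. A part played by it stays open. Against SUDHL5, 14 of the 21 genes responded more negatively in the mutant lines and 4 more positively, or 13 and 4 with the medians set to 0. That contrast includes WSUDLCL2 itself, and dose differs in it. SUDHL4 carries Y641S and WSUDLCL2 carries Y641F, so a role of Y641F itself cannot be told apart from other traits of WSUDLCL2. A fall shared by genes of this level remains open: the list median lay at percentile 41.1 of random lists matched on level, whose median was -0.25, and 10 genes fell and 5 rose with the median change of genes at 7 TPM or more set to 0. Whether that wider fall is of RNA per cell or of the scaling may need spike-in controls or cell counts. Lower NF-kB target expression in this line also remains open as a source.

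Increases made up 93.1%, 96.1% and 97.5% of the changes of 2-fold or more in HBL1, SUDHL4 and SUDHL5, and 72.2% in WSUDLCL2. At the floor of the log2(TPM + 1) scale, silent genes can rise and not fall. That floor is not the only source of the increases in the first 3 lines. Among genes at 7 TPM or more with DMSO, the lowest lower limit (95%, Wilson) over those lines and 3 scalings was 76.7%. That limit takes genes as independent. Most increases of 2-fold or more lay below 7 TPM: 154 in HBL1, 357 in SUDHL4 and 227 in SUDHL5, against 61, 59 and 44 at that level. For the lower genes this test cannot decide, because the floor acts there. In WSUDLCL2 the floor cannot be told apart from other sources, since among genes at 7 TPM or more with DMSO the share of increases was 28.7% (166 against 413), 42.8% without mitochondrial genes and 63.2% with the median change of genes at 7 TPM or more set to 0. Release of genes silenced by PRC2 cannot be told apart from other sources of increases here, since the developmental target list lay above random lists in 1 of 4 lines and passed by cameraPR in 3 of them (adjusted p = 0.00434 in WSUDLCL2, 0.0387 in SUDHL4 and 0.0155 in SUDHL5), with 21 of its 49 genes at 1 TPM or more.

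Genes of short exon length with a single read in 1 library and none in its partners were counted. One HBL1 DMSO library, with 30.3 M reads or fragments, held 766 of them, against 491 and 503 in the deeper libraries, a ratio of 1.54 to their mean. Longer genes, and genes with more reads in that library alone, were not counted. Lower depth does not account for this, because the shallowest library of each of the other 7 groups held fewer such genes than the mean of its partners, with a highest ratio of 0.956. No biological explanation was tested. Reads from another sample or cell type may be a source and could not be tested without that library's values.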

How the results depend on the processing

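The alternatives limma-trend, the 5 TPM filter, both rescalings, joint adjustment, the unmoderated and z tests, the unfiltered contrasts, cameraPR and the limma mean response were chosen after seeing the data. No paired analysis was possible because the deposited table holds group means and no value per library. For the same reason leaving out replicates, other library normalizations, other pseudocounts, count-based tests, fits on the compared libraries alone, an estimated correlation for gene lists and RLE-scaled baselines were not run. Counts at an adjusted p under 0.01, with limma-trend, at 5 TPM or more, under both rescalings and under joint adjustment stayed within 1.5 times the reported ones for each line, for the genes called in all 4 lines and, where run, for the 3 differences of response, which also held for the unmoderated and z tests and with no level filter. Requiring a 2-fold change as well left 231 genes in HBL1, 1740 in WSUDLCL2, 433 in SUDHL4 and 278 in SUDHL5, 6 in all 4 lines, and 426, 532 and 809 for the differences between mutant and wild-type lines, mutant and wild-type germinal centre lines and the mutant lines, because small changes drop out by construction. The mean response over the 4 lines as a limma contrast called 11893 genes against 2091 called in every line, since a contrast needs no call in each line. Against unmatched random lists 27 of the 92 list tests passed, against 41 matched on level; the cause was not tested. Among single values, of the 13 always named genes 1 changed sign under a rescaling, BCL6 in SUDHL5, which was not a call, and B2M in SUDHL4 became a call under both. The class I list passed in SUDHL4 under both rescalings and missed the threshold in SUDHL5 against unmatched lists. Whether a depth of 26.7 M to 49.4 M limits the calls was not tested; the 15884 genes under 1 TPM in every group were left out of the differences of response.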

Other observations

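Single genes of several lists changed in lines where the text has not described them. In the integrated stress and unfolded protein response list, ASNS, which encodes asparagine synthetase, fell by 0.99 in WSUDLCL2, 0.60 in SUDHL4 and 0.56 in HBL1, and CHAC1 fell by 1.78 in WSUDLCL2, 1.03 in SUDHL4 and 0.64 in HBL1 in the authors' deposited table. The list as a whole missed the threshold in WSUDLCL2 (adjusted p = 0.117), SUDHL4 (adjusted p = 0.216) and HBL1 (adjusted p = 0.471), and by cameraPR it passed in HBL1 alone of these lines (adjusted p = 0.00947). Of the cholesterol biosynthesis genes 16 of 21 fell in WSUDLCL2, HMGCS1 by 1.04, but the list median of -0.29 was close to the -0.31 of random lists of that level (adjusted p = 0.883, against 0.0412 by cameraPR). Of the PRC2 components and H3K27 demethylases, JARID2 rose in all 4 lines, by 0.35 in HBL1, 0.71 in WSUDLCL2, 0.42 in SUDHL4 and 0.50 in SUDHL5, and SUZ12 fell by 0.65 in WSUDLCL2, 0.25 in SUDHL5, 0.22 in HBL1 and 0.21 in SUDHL4. That list did not pass in any line, with adjusted p from 0.142 to 0.989.

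Single ligand genes for NK cells and T cells differed between lines. MICB, a ligand of the activating receptor NKG2D, fell by 1.09 in WSUDLCL2 and CD80 by 1.31 there, while CD80 rose by 0.64 in SUDHL4 and 0.41 in HBL1. The galectin gene LGALS9 rose by 1.97 in WSUDLCL2, 1.53 in SUDHL4 and 0.47 in HBL1. CD70 fell by 1.21 in WSUDLCL2 and rose by 1.45 in SUDHL4 and 0.39 in HBL1. CLEC2D, which encodes a ligand of an inhibitory NK cell receptor, fell by 0.70 in HBL1, 0.86 in WSUDLCL2, 0.30 in SUDHL4 and 0.53 in SUDHL5. The NK cell ligand list did not pass in any line, the lowest adjusted p being 0.0985 in SUDHL5. Among lists of few measured genes, PRAME, a cancer testis antigen, went from 0.343 to 4.12 TPM in WSUDLCL2 and rose by 1.08 in SUDHL4, DCN, a stromal marker, rose by 1.98 in WSUDLCL2 and PECAM1 by 1.21 in WSUDLCL2, 0.84 in SUDHL4 and 0.82 in SUDHL5. The lists of cancer testis antigens (5 genes measured) and of epithelial and stromal markers (6 genes) passed against random lists in no line, though the latter passed by cameraPR in HBL1 (adjusted p = 1.07e-07) and WSUDLCL2 (0.0163), and T cell markers (5 genes) passed in SUDHL5 alone. The median and mean of the T cell list had opposite signs in WSUDLCL2, at 0.21 and -0.08.

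The mitochondrial transcript list lay above random lists in all 4 lines, with medians of 0.51 in WSUDLCL2, 0.40 in HBL1, 0.12 in SUDHL4 and 0.07 in SUDHL5. The genes that passed alone were 7 of 13 in WSUDLCL2, 1 in HBL1, 1 in SUDHL4 and 0 in SUDHL5, and cameraPR, which takes the SE into account, gave adjusted p of 0.348, 0.623, 0.848 and 0.692.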
